A study of Mus musculus with 9 samples.

How the data were processed

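RNA-seq of 9 HC11 libraries was analysed from 1 table of raw counts per gene, which the authors deposited with a column per library, named by group and replicate as in the labels. Per the submitters' processing notes, Bowtie 0.12.2 and the mouse build mm8 were used. The coordinates in the table, however, equal those of GENCODE mouse release 21, on build GRCm38, in start and end for 53499 of the 54409 gene IDs found there (98.3%), so all coordinates here are GRCm38. The counter, its strand setting and any filter on the deposited counts are not given in the sources used here. The values are whole numbers with different totals per library, and no other sample's column was present. A column of gene length from the authors' table was not used in any test. The series title names human breast epithelium, while the organism label, the design text and the gene IDs are mouse. The title and the protocol name a laser, and the design text an LED.

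Libraries were grouped by the titles in the labels, with 3 each of Ctrl, EpPT1 and EpPT2. The 3 comparisons between groups, a test for a difference in any group and the correlation of the fold changes against Ctrl were fixed, with their tests, the gene lists, the rule for named genes and most of the alternatives, before the data were examined. In R 4.3.3, edgeR 4.0.16 was run on the counts with TMM scaling, its default filter on low counts (filterByExpr), 1 fit for all 9 libraries without a block (6 residual degrees of freedom) and the quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05. All tests were two-sided. Of 28724 genes with a count, 14471 were tested. Standard errors were derived from the fitted log2 fold change and its F statistic. CPM values are TMM-scaled unless said to be unscaled, and floors are unscaled. A count of 0 was taken to allow up to 3 counts, or 0.174 to 0.206 CPM by library; no molecular identifiers are recorded, so such floors cover counting error only.

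A total of 37 gene lists was fixed, covering stress, cell cycle, metabolic, signalling and mammary genes, and markers of fibroblasts, fat cells, and blood and immune cells. The 34 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, at the preset correlation of 0.01 and again with an estimated correlation, and with fry, whose p tests whether a list's genes move, on balance, one way. The list of opsins and cryptochromes had 4 tested members, led by Cry1 at up to 62.8 unscaled CPM, and was not tested. Median, mean and camera direction differed in sign for 7, 6 and 5 of the 34 lists in EpPT1 against Ctrl, EpPT2 against Ctrl and EpPT2 against EpPT1, with camera adjusted p values of 0.581, 0.816 and 0.599 or above. List members were also adjusted over the list alone.

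Named genes are those past the test with the largest fold changes, a mean of at least 5 CPM and non-overlapping groups. Where fewer than 4 passed in a direction, genes with the smallest p that met the other criteria filled up to 4 and are said not to pass. Added to these were up to 4 members with the smallest p of each list called by camera, and Hmox1, Fos, Egr1, Cdkn1a, Mki67, Per1, Csn2, mt-Co1, Cox4i1 and Krt8. Predicted genes and pseudogenes were left out of the rule, and 1 gene that it names is not reported here.

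The gene tests, the list test and the GC correction were tested on simulated data, drawn from the real means and library sizes for 14471 genes. For the gene and list tests 200 genes were changed, and the other members of the cholesterol synthesis list were raised 2-fold. Camera called that list and 0 others in each comparison. Each gene was drawn independently, so this could not test the preset correlation. At 4-fold changes edgeR recovered 45%, 53% and 54% of genes in EpPT1 against Ctrl, EpPT2 against Ctrl and EpPT2 against EpPT1, and at 2-fold changes 0%, 5% and 5%, with 8.16%, 11.8% and 9.09% false calls. DESeq2 1.42.0 recovered 68%, 72% and 69% at 4-fold changes, with 34.6%, 29.2% and 28.5% false calls. A GC trend added to simulated counts brought 9.54% of genes to an unadjusted p under 0.05, and 4.89% after correction. No pair of libraries was alike within sampling noise, with a lowest chi-square per gene of 5.10. Pearson's r of log2 CPM was 0.921 to 0.990 within groups and 0.904 to 0.991 between groups.

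Alternatives were DESeq2 size factors in place of TMM, no filter, a filter of 5 CPM in 3 libraries, DESeq2, limma-voom, glmTreat against a fold of 1.2, the replicate number as a block, only the 6 libraries compared, and leaving out each library in turn. Added after the data were seen were a GC correction, in which a spline with 5 degrees of freedom on gene GC content (13 tested genes had none) was removed per library as an offset, the mitochondrial share as a covariate, both together, and fits to libraries with under 5% mitochondrial counts or with GC slopes of one sign. The division of the Ctrl libraries 1 against 2 for the correlation of fold changes was also added then. DESeq2 size factors moved the median log2 fold change of all genes by less than 0.1.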

Results

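RNA was sequenced from HC11 cells, a mouse mammary epithelial line, in 3 groups of 3 libraries. One group was untreated (Ctrl) and the other groups, EpPT1 and EpPT2, were exposed to 660 nm light. The sample labels give 10 J/cm2 for EpPT1 and 20 J/cm2 for EpPT2, whereas the treatment protocol names 0.5 and 1 J/cm2 from a 10 mW laser, so the groups are named here without a dose. The time from exposure to lysis is not given in the sources used here. Total counts were 15867162, 16095370 and 14768299 in Ctrl, 17228929, 16979227 and 14674704 in EpPT1 and 15809059, 15183508 and 14549787 in EpPT2. Of 54532 genes in the table, 14471 were abundant enough to test. The biological coefficient of variation was 39.3%, and the median standard error of a log2 fold change against Ctrl was 0.37, so that 2 standard errors corresponded to a 1.67-fold difference. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

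All 9 libraries carried transcripts of luminal keratins. The luminal keratin Krt8 (ENSMUSG00000049382, chromosome 15, 101996698 to 102004482, GRCm38) reached 721 ± 145 CPM (counts scaled to the effective library size) in Ctrl, 738 ± 34.7 in EpPT1 and 695 ± 82.0 in EpPT2 (mean ± SD, n = 3 each). Its partner Krt18 lay between 760 and 1127 CPM in the 9 libraries. The epithelial gene Epcam had 17.8 to 44.1 unscaled CPM. The intermediate filament gene Vim had 586 to 2746 CPM and the fibroblast marker Dcn 733 to 3288 CPM. The milk protein genes Csn2 and Wap had 0 counts in every library, which allows up to 0.206 CPM in the shallowest one and covers counting error only. The casein gene Csn3 was present, at 23.0 to 104 CPM. The fibroblast marker list, with 5 members tested, had camera adjusted p values of 0.92, 0.816 and 0.512 in the 3 comparisons, with medians of −0.13, 0.20 and 0.09. Of the fat cell and the blood and immune cell markers, 3 each were abundant enough to test, led by Lpl at up to 409 CPM and Cd68 at up to 102 CPM, so neither list was tested.

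The largest difference between libraries did not follow the groups. The first principal component held 53.6% of the variance and placed Ctrl 3, EpPT1 3, EpPT2 2 and EpPT2 3 at 48.9 to 64.9, and the other 5 libraries at −73.0 to −35.8. Those 4 libraries also had 6.06% to 7.48% of their counts on mitochondrial genes, against 2.74% to 3.62% in the other 5. The second component, with 21.6% of the variance, placed the 3 Ctrl libraries and EpPT1 1 at 12.5 to 48.3 and the 5 remaining libraries at −45.1 to −12.8, and its gene loadings had a Spearman correlation of −0.56 with GC content across genes, which are not independent replicates.

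**Figure D1:**
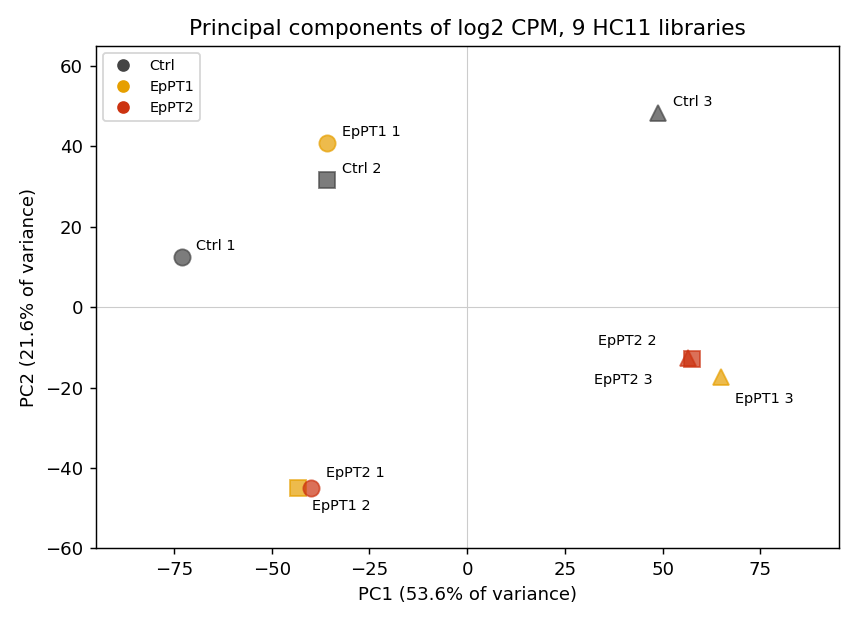
Principal components of log2 CPM for 9 HC11 libraries, with PC1 (53.6% of the variance) on the x axis and PC2 (21.6%) on the y axis; colour gives the group, shape the replicate (circle, square and triangle for 1, 2 and 3), and each point is a library. Ctrl 3, EpPT1 3, EpPT2 2 and EpPT2 3 lie at 48.9 or above on PC1, and EpPT1 1 lies among the Ctrl libraries on PC2; the points of EpPT2 2 and EpPT2 3 nearly coincide.

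Genes rich in GC had higher values in most exposed libraries. The slope of log2 expression on gene GC content was −0.495, −0.223 and −0.232 per 10 percentage points in Ctrl, −0.355, 0.179 and 0.368 in EpPT1, and 0.186, 0.291 and 0.280 in EpPT2. Fold changes against Ctrl had a Spearman correlation with GC content of 0.60 for EpPT1 and 0.62 for EpPT2 across genes. The library EpPT1 1 thus had a slope within the Ctrl range, unlike EpPT1 2 and EpPT1 3.

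**Figure D2:**
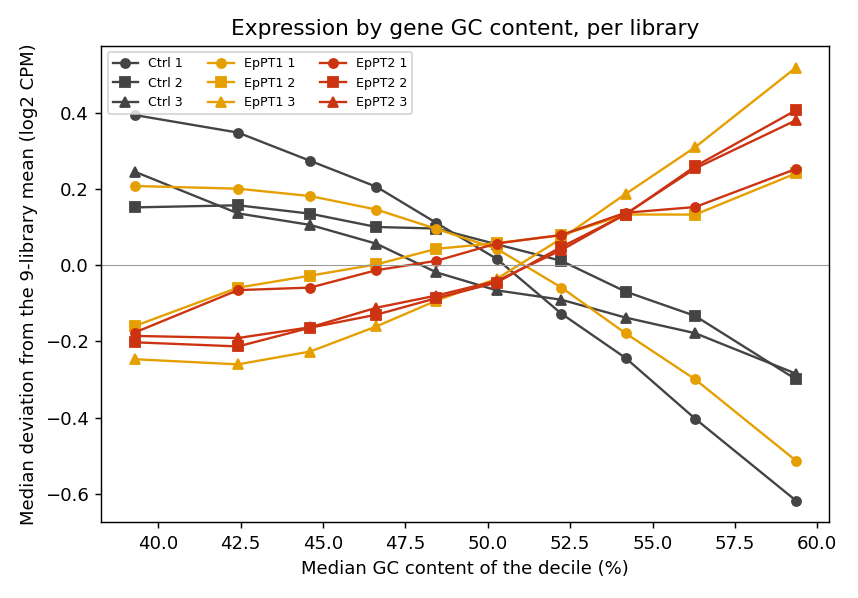
Median deviation from the mean of the 9 libraries (y axis, log2 CPM) in 10 classes of genes ordered by GC content (x axis, median GC of the class in percent), with a line per library, coloured by group. Lines of the Ctrl libraries and EpPT1 1 fall with GC content (slopes −0.495 to −0.223 per 10 points) and those of the other 5 libraries climb (0.179 to 0.368).

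The comparison of EpPT1 with Ctrl addresses what the exposure with the lower labelled fluence did to the transcriptome. No gene passed the test, and the 8 genes named next have the smallest p among those with non-overlapping groups and a mean of at least 5 CPM. Zfp628, which encodes a zinc finger protein (ENSMUSG00000074406, chromosome 7, 4915217 to 4922002, GRCm38), had 9.73 ± 1.12 CPM in Ctrl and 24.2 ± 9.34 in EpPT1 (mean ± SD, n = 3 each), a log2 difference of 1.31 (SE 0.32). Fbxl15, an F-box subunit of a ubiquitin ligase, gave 1.70 (SE 0.43), Taf1c, a subunit of the RNA polymerase I selectivity factor, 1.47 (SE 0.37), and Aldh16a1, of the aldehyde dehydrogenase family, 1.32 (SE 0.35). Lower in EpPT1 were Zfp52 at −0.95 (SE 0.28), the COPII coat gene Sec23a at −1.06 (SE 0.34) and the centrosomal gene Cep170 at −0.65 (SE 0.21). Rps27rt, at −1.43 (SE 0.38), shares reads with Rps27, so its value is uncertain, and without the filter on low counts it passed edgeR's test (adjusted p = 0.0070). In each of these 8 genes the 3 libraries of EpPT1 lay outside the range of Ctrl, and edgeR's quasi-likelihood test gave all of them an adjusted p of 0.991. The 4 higher genes have 56.0% to 63.7% GC and the 4 lower ones 39.9% to 46.0%.

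Immediate early genes, which respond within minutes to growth factors and stress, came closest to a call among the fixed lists. Their median log2 difference was 0.36, with 18 of 26 members higher, and camera gave an adjusted p of 0.061. Ribosome biogenesis genes had a median of 0.20, with 23 of 32 higher (adjusted p = 0.062), and genes of the integrated stress response a median of 0.21, with 18 of 24 higher (adjusted p = 0.082). Among the genes fixed in advance, the haem oxygenase gene Hmox1 differed by 0.98 (SE 0.62), Fos by 0.73 (SE 1.07), Egr1 by 0.40 (SE 0.64) and the clock gene Per1 by 0.95 (SE 0.37). The cell cycle inhibitor Cdkn1a (0.15, SE 0.27), the proliferation marker Mki67 (0.08, SE 0.34) and Krt8 (0.03, SE 0.21) lay nearer to 0. Of cytochrome c oxidase, often proposed as an absorber of red light in cells, mt-Co1 differed by −0.38 (SE 0.61) and Cox4i1 by −0.03 (SE 0.19). Without EpPT1 3, Fos gave −0.89 and Egr1 −0.31, and without Ctrl 3, mt-Co1 gave 0.46.

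edgeR called 0 of 14471 genes in EpPT1 against Ctrl (lowest adjusted p = 0.991), with 568 genes at an unadjusted p under 0.05, 435 of them higher, where 724 would be due to chance. DESeq2 called 1 gene, the pseudogene Got2-ps1 at −3.21, named after its values were seen, and limma-voom called 0, with 736 and 407 genes at an unadjusted p under 0.05. The groups did not overlap in 5.26% of genes, against 10% by chance. Other splits of these 6 libraries gave 28 to 2914 genes at an unadjusted p under 0.05 in edgeR, so the 724 says little about chance here. Camera called 0 of 34 lists, as it did with an estimated correlation (lowest adjusted p = 0.841) and as fry did (lowest adjusted p = 0.847), and 0 list members passed edgeR's test over all genes or adjusted over the list alone. At the preset correlation, camera called immediate early genes higher with the stricter filter (adjusted p = 0.019) and the replicate block (0.022). It also did so with only the 6 libraries compared (0.028) and with the mitochondrial covariate (0.022). Ribosome biogenesis genes were called in all of these but the last (camera adjusted p = 0.019 to 0.044). The integrated stress response was called with the block (0.044) and the 6 libraries (0.039). The immediate early list was not called after the trend with GC content was removed, nor without Ctrl 1, Ctrl 2, EpPT1 2 or EpPT1 3. It was called without Ctrl 3, EpPT1 1 or EpPT2 1. Its score was 0.52 in Ctrl 3, above every EpPT1 library, and −0.76 in EpPT1 1. Leaving out 1 library moved the camera count to 4 without Ctrl 1, 7 without Ctrl 3, 2 without EpPT1 1, 1 without EpPT1 2, 7 without EpPT1 3 and 2 without EpPT2 1, and the count at an unadjusted p under 0.05 to 1980 without EpPT1 1, 355 without Ctrl 1, 231 without EpPT1 2 and 253 without EpPT1 3. That count was also 1974 with the mitochondrial share of each library as a covariate, and 947 with a replicate block. It fell to 270 after the trend with GC content was removed, 266 with only the 6 libraries compared and 186 with only the 5 libraries of a low mitochondrial share. In simulated counts of the same depth and spread, edgeR found 45% of 4-fold and 0% of 2-fold changes of this comparison.

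EpPT2 against Ctrl, the exposure with the higher labelled fluence, gave the most genes at an unadjusted p under 0.05 of the 3 comparisons in edgeR, and 0 passed the test. Camera called 4 lists at its preset correlation, and none of the 4 with an estimated correlation (adjusted p = 0.964 each). Immediate early genes were called higher, with 20 of 26 members higher and a median log2 difference of 0.61, but the call was lost with an estimated correlation (adjusted p = 0.964) and after the trend with GC content was removed. The AP-1 subunit Jund (ENSMUSG00000071076, chromosome 8, 70698949 to 70700616, GRCm38) had 45.8 ± 20.6 CPM in Ctrl and 161 ± 10.1 in EpPT2 (mean ± SD, n = 3 each), a log2 difference of 1.82 (SE 0.54). Ier5 (113 ± 14.4 against 221 ± 40.9 CPM), Ier2 (82.1 ± 5.96 against 141 ± 4.71 CPM) and the transcription factor Klf4 (210 ± 133 against 433 ± 116 CPM) differed by 0.97 (SE 0.34), 0.78 (SE 0.29) and 1.05 (SE 0.47). The extracellular matrix list was called higher (25 of 31 members, median 0.48) and that of G2/M and mitosis genes lower (26 of 36, median −0.37), in both cases with an adjusted p = 0.964 with an estimated correlation. Both scores followed the 4 libraries with a high mitochondrial share: the matrix score was 0.27 in Ctrl 3 and −0.19 in EpPT2 1, and the G2/M score −0.33 in Ctrl 3, below all 3 EpPT2 libraries, and 0.062 in EpPT2 1. Among the other libraries the G2/M score was 0.38 and 0.30 in Ctrl 1 and Ctrl 2. Without the 4, EpPT2 1 is alone in its group, so these values give a direction and no test. The G2/M score was 0.35 in EpPT1 1 and 0.040 in EpPT1 2, which differ in the sign of their GC slope. The G2/M call was also lost after the trend with GC content was removed.

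Within the matrix list, the metalloproteinase gene Mmp14 differed by 0.54 (SE 0.24) and the metalloproteinase inhibitor Timp2 by 0.48 (SE 0.21). Mmp3 (2.19, SE 0.73) and the collagen gene Col5a3 (1.45, SE 0.67) were near the detection limit, with Ctrl means of 0.248 and 0.539 CPM. The lower mitotic genes included Ndc80, of the outer kinetochore (ENSMUSG00000024056, chromosome 17, 71496100 to 71526857), at 88.4 ± 5.11 CPM in Ctrl and 52.4 ± 1.23 in EpPT2 and a log2 difference of −0.75 (SE 0.26). The spindle checkpoint kinase gene Bub1 gave −0.74 (SE 0.27), the spindle gene Hmmr −1.06 (SE 0.41) and the cytokinesis gene Anln −0.63 (SE 0.25). Mki67 gave 0.47 (SE 0.34), but −0.21 without the 4 libraries with a high mitochondrial share, where EpPT2 1 is alone in its group. Small nucleolar RNA host genes were called higher as a list, with 10 of 13 higher and a median of 0.42, but not with an estimated correlation (adjusted p = 0.964), and their score too was high in Ctrl 3 (0.31) and low in EpPT2 1 (−0.14). That list, as fixed, also names the long noncoding RNAs Malat1 and Neat1, which are not host genes. Members with the smallest p were Epb41l4aos (1.03, SE 0.31), Snhg12 (0.91, SE 0.37), Snhg17 (0.75, SE 0.31) and Snhg20 (1.27, SE 0.61). Epb41l4aos is an antisense transcript and the strand setting of the counts is not given, so its value is uncertain.

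Among the genes that the rule for single genes names, Zfp628 had the smallest p, at 28.2 ± 3.06 CPM in EpPT2 and a log2 difference of 1.53 (SE 0.32). Close to it were Rce1, a protease that processes prenylated proteins, at 1.36 (SE 0.29), Armc5 at 1.44 (SE 0.31) and Fbxl15 at 2.02 (SE 0.43). On the lower side Zfp52 gave −1.32 (SE 0.28), Cep170 −0.92 (SE 0.21), Pcmtd1 −0.93 (SE 0.23) and Gfpt1, the first enzyme of hexosamine synthesis, −1.05 (SE 0.27). Each had non-overlapping groups and an adjusted p of 0.376 in edgeR, so none passed there, and again the 4 higher genes are GC-rich (57.2% to 63.7%) and the 4 lower ones GC-poor (38.9% to 44.4%). In DESeq2 all of them but Gfpt1 passed (adjusted p = 0.014 to 0.042). Without the filter on low counts edgeR called Zfp628, Rce1, Armc5, Fbxl15, Jund, Snhg20, Hmox1 and Fos (adjusted p = 4.0e-05 to 0.042). Of these, Snhg20, Hmox1 and Fos had overlapping groups. With the filter their unadjusted p in edgeR was 0.062, 0.095 and 0.26. The genes fixed in advance gave 1.15 (SE 0.62) for Hmox1, 1.29 (SE 1.08) for Fos, 1.11 (SE 0.64) for Egr1, 0.96 (SE 0.37) for Per1, 0.06 (SE 0.27) for Cdkn1a, 0.02 (SE 0.61) for mt-Co1, −0.05 (SE 0.19) for Cox4i1 and −0.05 (SE 0.21) for Krt8.

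**Figure D3:**
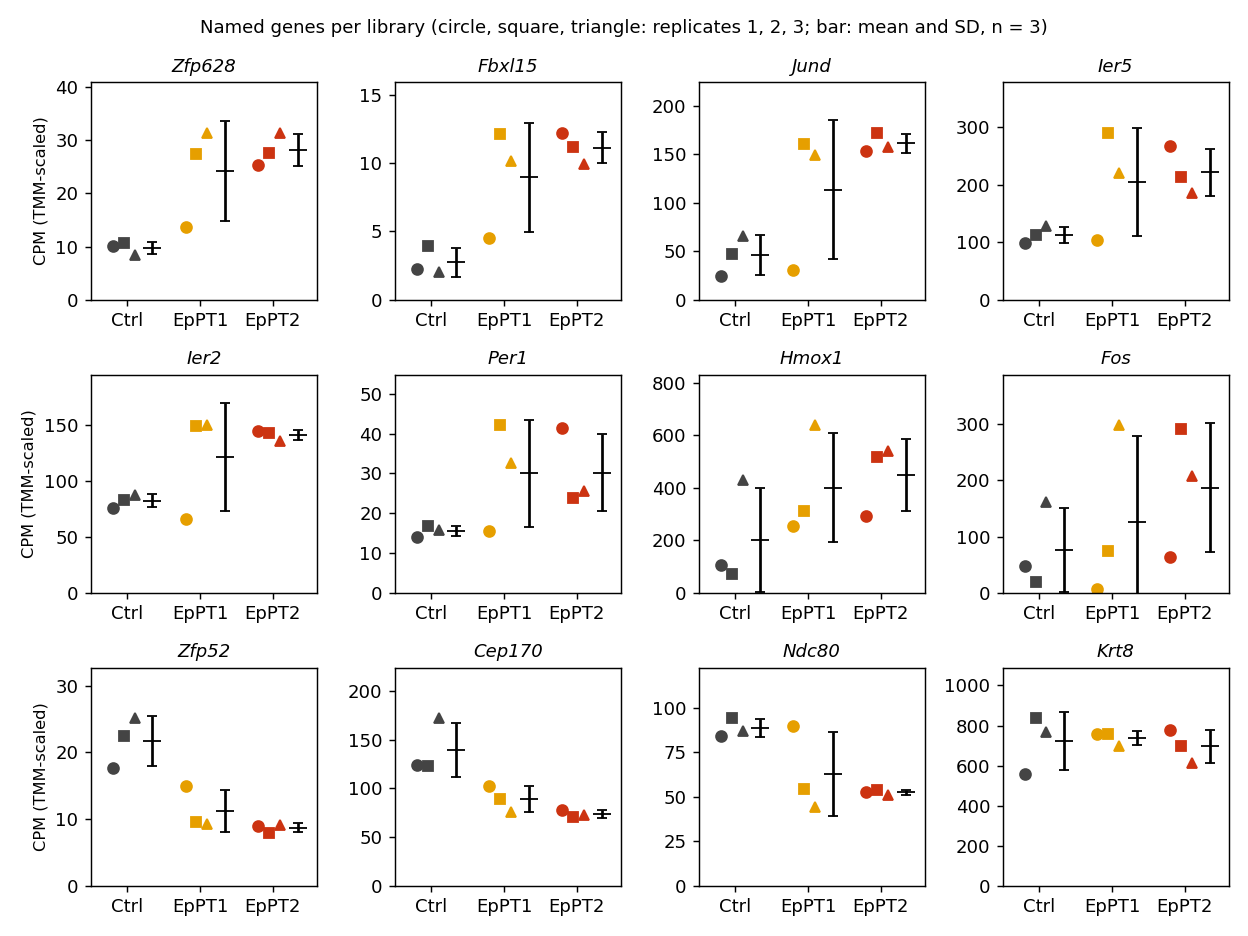
TMM-scaled CPM (y axis, from 0) of 12 named genes in the 9 libraries, with a marker per library (circle, square and triangle for replicates 1, 2 and 3), a bar for the mean and error bars of 1 SD (n = 3), which are clipped at 0 for Fos. Jund has 45.8 ± 20.6 CPM in Ctrl and 161 ± 10.1 in EpPT2, and Krt8 has 721 ± 145 and 695 ± 82.0; no gene passed the test.

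edgeR called 0 of 14471 genes in EpPT2 against Ctrl (lowest adjusted p = 0.376), with 1763 genes at an unadjusted p under 0.05, 995 higher and 768 lower, where 724 would be due to chance. DESeq2 called 62 genes, 52 of them higher, and limma-voom called 0, with 2163 and 1757 genes at an unadjusted p under 0.05. Without the filter on low counts edgeR called 268 genes, all of them among the 14471, and 46 of the 62 DESeq2 genes were among these. The groups did not overlap in 23.2% of genes, against 10% by chance. Other splits of these 6 libraries gave 41 to 4493 genes at an unadjusted p under 0.05 in edgeR, a range that holds the real 1763. The 4493 came from setting Ctrl 1, Ctrl 2 and EpPT2 1 against the rest, which follows the mitochondrial share. With that share as a covariate, added after the data were seen, the other splits gave 82 to 1050 and the real one 3533. The 10 splits are too few for a share under 0.05. Without EpPT1 1, which enters through the shared estimate of the spread, edgeR called 2 genes, Rpl23a at 2.44 and the ribosomal protein pseudogene Gm8210 at 3.75, both named after their values were seen and both uncertain because near-identical copies share their reads. The count at an unadjusted p under 0.05 was 1004 without Ctrl 1, 834 without EpPT2 2 and 858 without EpPT2 3. It was 3533 with the mitochondrial share as a covariate (lowest edgeR adjusted p = 0.097) and 3056 with a replicate block (lowest edgeR adjusted p = 0.068). It fell to 898 after the trend with GC content was removed and to 590 with only the 5 libraries of a low mitochondrial share, where EpPT2 1 is alone in its group.

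Camera called 4 of 34 lists in EpPT2 against Ctrl, with adjusted p values of 0.0098 for immediate early, 0.013 for extracellular matrix and 0.042 for both the small nucleolar RNA host and the G2/M genes. None of the 4 calls held with an estimated correlation, where each had an adjusted p of 0.964, and fry gave each an adjusted p of 0.79. Over all genes 0 list members passed edgeR's test, and 7 passed when adjusted over the list alone, in lists that camera did not call. These were Bax (0.84), Trp53inp1 (−0.96), Polk (−0.96), Plk3 (1.10) and Bbc3 (1.84) of the p53 list and mt-Cytb (0.88) and mt-Nd4l (1.61) of the mitochondrial genome list, each with an adjusted p of 0.376 over all genes. Camera called 0 lists without Ctrl 1 or without Ctrl 2, 7 without EpPT2 1, and only the immediate early list without EpPT2 2 or without EpPT2 3. After each library's trend with GC content was removed, immediate early, extracellular matrix and G2/M genes were no longer called, and Ier2 gave −0.092. There the small nucleolar RNA host list (adjusted p = 0.00026) and the mitochondrial genome list (adjusted p = 3.4e-06) were called by camera, though not with an estimated correlation (adjusted p = 0.985 each). With the mitochondrial share of each library as a covariate, camera called the immediate early list alone (adjusted p = 0.027, or 0.920 with an estimated correlation).

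**Figure D4:**
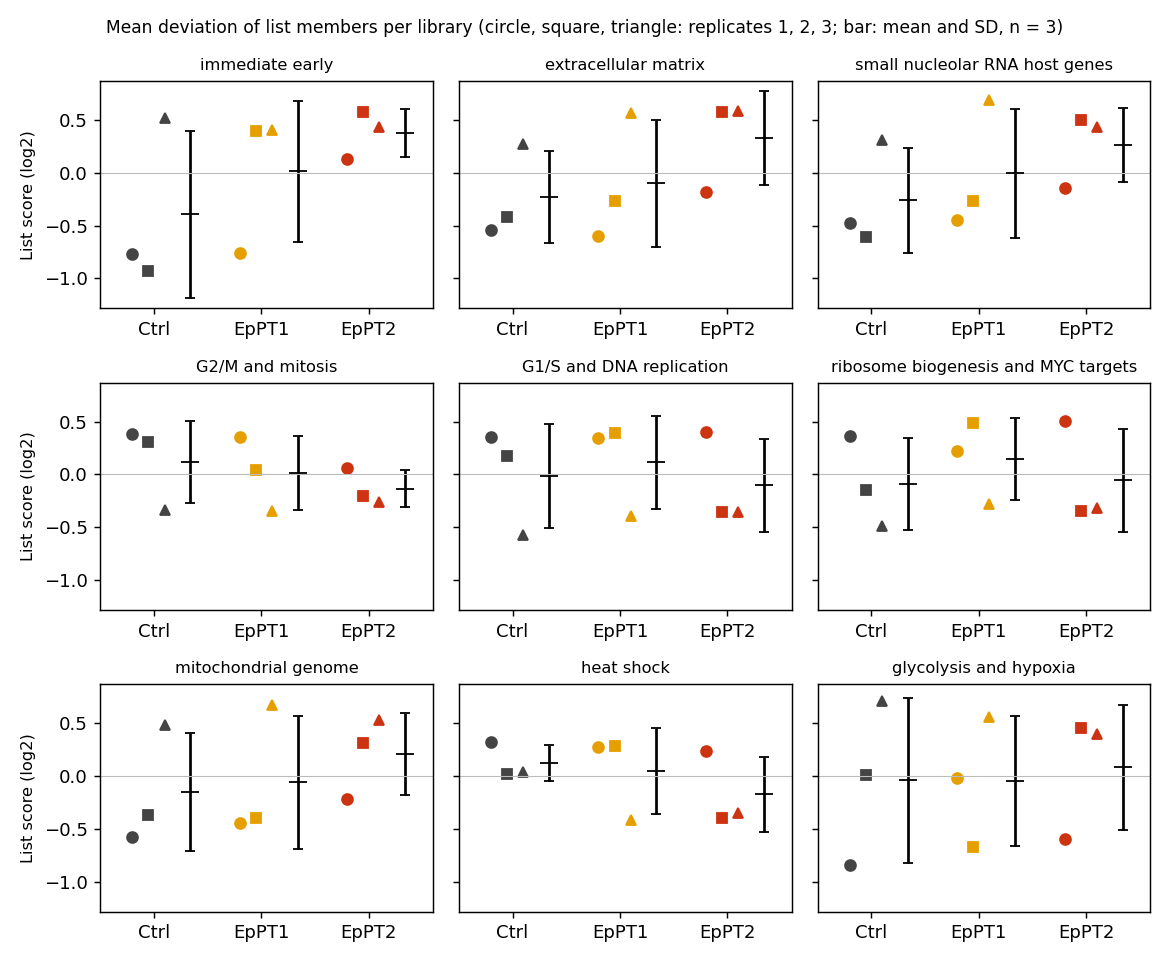
Mean deviation of list members from the 9-library mean (y axis, log2) for 9 gene lists, with a marker per library (circle, square and triangle for replicates 1, 2 and 3), a bar for the mean and error bars of 1 SD (n = 3). The immediate early score is 0.13 to 0.57 in EpPT2 but also 0.52 in Ctrl 3, and the extracellular matrix score is 0.27 to 0.59 in Ctrl 3, EpPT1 3, EpPT2 2 and EpPT2 3 and −0.60 to −0.19 in the other 5 libraries.

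EpPT2 against EpPT1 compares the exposures with each other. Camera called 6 lists at its preset correlation, of which none was called with an estimated correlation (adjusted p = 0.789 each) or with the mitochondrial share of each library as a covariate. Extracellular matrix genes were called higher in EpPT2, with 29 of 31 members higher and a median log2 difference of 0.30, as were the 13 protein genes of the mitochondrial genome, with 9 higher, 4 lower and a median of 0.20 (each adjusted p = 0.789 with an estimated correlation). Called lower were genes of DNA replication and the G1/S transition (32 of 35 lower, median −0.25), G2/M and mitosis (29 of 36, median −0.20), ribosome biogenesis (27 of 32, median −0.17) and heat shock (13 of 15, median −0.18), again each with an adjusted p = 0.789 with an estimated correlation. No member passed edgeR's test. In the matrix list Sparc, a collagen-binding glycoprotein, had 254 ± 66.8 CPM in EpPT1 and 318 ± 64.1 in EpPT2 (mean ± SD, n = 3 each), a log2 difference of 0.32 (SE 0.26), and Fbln1 gave 0.63 (SE 0.43), Col6a3 0.85 (SE 0.55) and Mmp3 0.98 (SE 0.68).

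Of the replication genes, the sliding clamp gene Pcna differed by −0.26 (SE 0.21), Slbp by −0.30 (SE 0.23), the polymerase gene Pola1 by −0.53 (SE 0.45) and the helicase subunit Mcm4 by −0.55 (SE 0.46). Hmmr (−0.62), Nusap1 (−0.53), Bub1 (−0.36) and Anln (−0.30) were the mitotic genes with the smallest p, and Ddx21 (−0.40), Wdr43 (−0.27), Wdr12 (−0.56) and Nop16 (−0.45) those of ribosome biogenesis. The chaperone genes Hsph1 (−0.68), Hspd1 (−0.36), Hspe1 (−0.39) and Hsp90aa1 (−0.40) were lower, and Hspd1 and Hspe1 overlap on chromosome 1, so that their reads may be shared. In the mitochondrial genome mt-Nd4l (chromosome MT, 9877 to 10173) gave 1.10 (SE 0.41), mt-Nd4 0.36, mt-Cytb 0.26 and mt-Atp8 −0.66, or 0.17 without EpPT1 3. The value of mt-Nd4l is uncertain because it overlaps mt-Nd4, which starts at 10167. Genes named for a small p, a mean of at least 5 CPM and non-overlapping groups were Dynlt1c (0.97, SE 0.40), which has near-identical copies, Tmem216 (0.57), Styk1 (0.45), Qpctl (0.61), Lrba (−0.64), Trmt10b (−0.51) and Lrch3 (−0.62). The genes fixed in advance gave 0.17 for Hmox1, 0.56 for Fos, 0.71 for Egr1, −0.08 for Cdkn1a, 0.39 for Mki67, 0.01 for Per1, 0.40 for mt-Co1, −0.02 for Cox4i1 and −0.08 for Krt8.

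edgeR called 0 of 14471 genes in EpPT2 against EpPT1 (lowest adjusted p = 1.00), with 31 at an unadjusted p under 0.05 where 724 would be due to chance, and DESeq2 and limma-voom called 0, with 38 and 22. The groups did not overlap in 2.45% of genes, against 10% by chance. Other splits of these 6 libraries gave 32 to 5666 genes at an unadjusted p under 0.05 in edgeR, where the real split gave 31. Leaving out 1 library, 182 genes were at an unadjusted p under 0.05 without EpPT2 1, 67 without EpPT1 2 and 709 without EpPT1 3, but 17 without EpPT2 3 and 19 without EpPT2 2. That count was 173 with a replicate block, 89 with the mitochondrial share as a covariate and 54 with only the 5 libraries of a low mitochondrial share. Camera called 6 of 34 lists, with adjusted p values of 8.2e-05 for extracellular matrix, 0.0050 for G1/S, 0.014 for both G2/M and ribosome biogenesis, 0.019 for the mitochondrial genome and 0.025 for heat shock. None held with an estimated correlation, where each had an adjusted p of 0.789, and fry gave each an adjusted p of 0.89; 0 members passed edgeR's test over all genes or adjusted over the list alone. Camera called 0 lists without EpPT1 1, only the extracellular matrix list without EpPT2 2 or without EpPT2 3, 10 without EpPT1 3 and 12 without EpPT2 1. Without EpPT1 2 only the extracellular matrix list of the 6 was still called (camera adjusted p = 0.031), beside lists outside the 6. After the trend with GC content was removed, the G2/M call was lost. The other calls stayed at the preset correlation, with a camera adjusted p of 0.890 each with an estimated correlation. Of the 4 libraries with a high mitochondrial share, EpPT2 holds 2 and EpPT1 holds 1, and with that share as a covariate none of the 6 lists was called, while glycolysis and hypoxia genes were (lower, adjusted p = 0.019, or 0.993 with an estimated correlation).

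Fold changes of EpPT1 and EpPT2 against the same Ctrl libraries were correlated across genes, which are not independent replicates. Pearson's r was 0.833 for the fitted values and 0.817 for differences of mean log2 CPM, and 83.3% of genes had the same sign. Because both use the same Ctrl libraries, 20 simulations with no effect gave an r of 0.503 and 66.8% with the same sign. The covariance was 0.217, against 0.135 in the simulations. The simulations drew each gene independently, whereas genes of the real libraries vary together. They therefore do not show how far r can lie from 0.503 with no effect. No division of 3 Ctrl libraries leaves 2 on each side. Divided 1 against 2, so that no library was shared, the 6 possible divisions gave an r of −0.198 to 0.412 and a covariance of −0.119 to 0.157. The covariance was above 0 in 5 of the 6, with a mean of 0.0638, and part of the excess may come from the shared controls. The fitted r was 0.366 without EpPT1 3, 0.662 without EpPT2 1, 0.719 without EpPT1 2 and up to 0.915 without Ctrl 3. Asked whether a gene differed in any group, edgeR called 0 genes (lowest adjusted p = 0.911, with 755 at an unadjusted p under 0.05), DESeq2 called 2, Got2-ps1 and the pseudogene Gm8129, named after their values were seen, and limma-voom called 0, with 1103 and 709 at an unadjusted p under 0.05.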

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

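The tests with a GC correction, with the mitochondrial share as a covariate or on selected libraries were chosen only after the data were seen. DESeq2 size factors, limma-voom and glmTreat left each count of genes called and, for the size factors, of lists and the correlation within 1.5 times the reported value, but glmTreat gave 366 genes at an unadjusted p under 0.05 in EpPT1 against Ctrl, against 568 reported. Without the low-count filter edgeR called 32 genes in EpPT1 against Ctrl (30 higher), 268 in EpPT2 against Ctrl (239 higher), 2 in EpPT2 against EpPT1 and 132 in any group. The pair of genes in EpPT2 against EpPT1 were Gm14632, at 38.1 unscaled CPM in EpPT1 1 alone, and Gm10488, at 7.77 unscaled CPM in EpPT2 3 alone, both named after their values were seen. In that setting 2 lists were called in EpPT2 against EpPT1 and the correlation of fold changes was 0.589. The stricter filter gave 2, 1 and 10 lists in EpPT1 against Ctrl, EpPT2 against Ctrl and EpPT2 against EpPT1. DESeq2 called 1, 62 and 0 genes in the same order and 2 in any group, with 31, 1434 and 31 adjusted p values not given. Only the 6 libraries compared gave 3 lists in EpPT1 against Ctrl. An estimated correlation gave 0 lists in EpPT2 against Ctrl and 0 in EpPT2 against EpPT1, and so did fry (0 and 0). In these cases the cause was not tested.

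Leaving out each library in turn gave 0 to 7 lists in EpPT1 against Ctrl, 0 to 7 in EpPT2 against Ctrl and 0 to 12 in EpPT2 against EpPT1, 0 to 2 genes in EpPT2 against Ctrl and a correlation of 0.366 to 0.915. In EpPT1 against Ctrl the log2 difference of mt-Co1 ranged from −1.01 to 0.46 (without Ctrl 3), that of Fos from −0.89 (without EpPT1 3) to 1.90 and that of Egr1 from −0.31 (without EpPT1 3) to 1.08. In EpPT2 against EpPT1 that of mt-Atp8 ranged from −1.01 to 0.17 (without EpPT1 3). With the replicate number as a block, 3 lists were called in EpPT1 against Ctrl and no other count of calls moved by over 1.5 times, but 947, 3056 and 173 genes were at an unadjusted p under 0.05 in EpPT1 against Ctrl, EpPT2 against Ctrl and EpPT2 against EpPT1, where 568, 1763 and 31 are reported. The numbers paired the libraries only in part. Same-numbered libraries had correlations of deviations of −0.64 to 0.73, over 0.1 in 6 of 9 pairs, and 4 of 9 libraries correlated best with their own number. Pairs numbered 1 had 0.15 to 0.73 and pairs numbered 3 had 0.63 to 0.73, but pairs numbered 2 had −0.64 to 0.06.

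The GC correction gave 3 lists in EpPT1 against Ctrl and 2 in EpPT2 against Ctrl, and turned Krt8 in EpPT1 against Ctrl (−0.25) and Ier2 (−0.092) and Cdkn1a (−0.25) in EpPT2 against Ctrl. The mitochondrial share as a covariate gave 1, 1 and 1 list in EpPT1 against Ctrl, EpPT2 against Ctrl and EpPT2 against EpPT1, with 1974, 3533 and 89 genes at an unadjusted p under 0.05 and 0 called by edgeR. Both together gave 1109, 2166 and 119 such genes, 3 lists in EpPT1 against Ctrl and 1 in EpPT2 against EpPT1, with Krt8 at −0.31 in EpPT1 against Ctrl and Ier2 at −0.047 and Cdkn1a at −0.23 in EpPT2 against Ctrl. In EpPT2 against Ctrl camera then called the mitochondrial genome and small nucleolar RNA host lists higher and glycolysis and hypoxia genes lower. The 5 libraries with under 5% mitochondrial counts, where EpPT2 1 is alone in its group and assumed to vary like the others, gave 6 lists in EpPT1 against Ctrl, 1 in EpPT2 against EpPT1 and a correlation of 0.605, with 186, 590 and 54 genes at an unadjusted p under 0.05 in EpPT1 against Ctrl, EpPT2 against Ctrl and EpPT2 against EpPT1. Under the GC correction, the covariate, both together and the fits to the 5 or the 4 libraries, camera with an estimated correlation called none of the lists called there. In the fit to the 5 libraries with under 5% mitochondrial counts, Mki67 turned to −0.21 and Krt8 to 0.17 in EpPT2 against Ctrl. Mki67 turned to −0.19 there in EpPT2 against EpPT1. The 5 libraries with a positive GC slope gave 0 lists in EpPT2 against EpPT1. The 4 with a negative slope gave 5 lists in EpPT1 against Ctrl and values of −3.36 for Fos, −1.18 for Egr1 and −0.00020 for Per1, but these rest on EpPT1 1 alone, with the spread taken from the 3 Ctrl libraries. Of 1873 values of named genes under all alternatives, 1841 kept their direction and side of the threshold or changed sign by less than 1 standard error (46), 16 turned, 16 passed the threshold (without the filter or with DESeq2). No named gene was called by edgeR as reported, so none had a call to lose. Mmp3, mt-Atp8 and Col5a3 had few counts. Whether depth or, for mt-Atp8, reads lost to the overlapping mt-Atp6 keeps them low was not tested.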

Other observations

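The tests of GC slopes, of Rpl23a, with the mitochondrial share as a covariate, of other cell types and of hypoxia genes were chosen only after the result was seen. Gdf15, a secreted stress protein of the integrated stress response, was singled out after its values were seen (ENSMUSG00000038508, chromosome 8, 70629393 to 70632456, GRCm38). It had 31.2, 54.9 and 84.8 CPM in Ctrl, 39.1, 299 and 241 in EpPT1 and 261, 222 and 251 in EpPT2, a log2 difference from Ctrl of 1.76 (SE 0.61) in EpPT1 and 2.10 (SE 0.62) in EpPT2, with edgeR adjusted p values of 0.991 and 0.376. With 61.3% GC its values divide as the GC slopes of the libraries do, EpPT1 1 lying in the Ctrl range. In the same list the transcription factors Atf4 and Atf5 differed by 1.16 and 1.35 in EpPT2 against Ctrl and the glutathione-degrading enzyme gene Chac1 by 1.88, whereas the amino acid enzymes Asns (−0.34) and Psat1 (−0.33) did not share that direction, and the list had a camera adjusted p of 0.125. Outside that list the tight junction gene Cldn3 (62.7% GC), also singled out after its values were seen, had 79.4, 176 and 214 CPM in Ctrl, 148, 221 and 617 in EpPT1 and 250, 576 and 562 in EpPT2, a log2 difference of 1.56 (SE 0.56) in EpPT2 against Ctrl, which did not pass.

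Several genes of known mammary and hypoxia biology followed the first principal component, not the groups. Vegfa, the main hypoxia-induced angiogenic factor, had 1125, 775, 554 and 533 CPM in Ctrl 3, EpPT1 3, EpPT2 2 and EpPT2 3 and 47.1 to 139 in the other 5 libraries. Ankrd37 had 43.5 to 174 CPM in those 4 and 2.36 to 7.27 in the other 5, the casein gene Csn3 95.3 to 104 against 23.0 to 30.6, and the basal keratin Krt14 16.7 to 20.4 against 3.60 to 8.31. The cholesterol synthesis gene Idi1 went the other way, at 2.29 to 3.60 against 9.99 to 46.0 CPM. The endoplasmic reticulum chaperone Hspa5 had 4223 CPM in Ctrl 3, 1523 to 1592 in the other 3 of the 4, and 643 to 827 in the other 5.

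Fold changes against Ctrl followed GC content, with positive GC slopes in EpPT1 2, EpPT1 3 and the 3 EpPT2 libraries. GC bias as the whole difference between EpPT2 and Ctrl remains open, since the values go both ways. Removing the trend left 6.21% of genes at an unadjusted p under 0.05, against 12.2% before, but with the mitochondrial share as a covariate it left 2166 of 14471 genes, against 3533 before. The other 9 splits of these 6 libraries gave 49 to 5256 such genes in edgeR after the removal, where the real split gave 898, and 116 to 1302 with the covariate as well. Rpl23a, whose reads a near-identical copy can take, was at least 3.90 times higher in unscaled CPM in these 5 libraries than in any of the other 4, and Rps26-ps1 at least 3.02 times higher in those 4. Both genes were picked because they divide the libraries in this way, so they favour neither a batch nor the light. The share of counts on 3 genes with ribosomal RNA sequence divided alike, at 0.0598% to 0.132% in the 5 and 0.00792% to 0.0157% in the 4, and may reflect RNA or library quality, which was not tested further. A difference between library batches or an effect of the light could account for the trend. Of the 6 exposed libraries, 5 had a slope above the highest Ctrl slope, 1 short of what an effect on all of them needs. For EpPT2 and Ctrl, treatment and batch cannot be told apart because all EpPT2 libraries lie on one side and all Ctrl libraries on the other. EpPT1 lies on both sides, with slopes of −0.355 in EpPT1 1 and 0.179 in EpPT1 2, but this rests on EpPT1 1 alone. A wrong label on EpPT1 1, which resembles Ctrl 2 with an r of 0.983, was not tested.

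The 4 libraries with 6.06% to 7.48% mitochondrial counts lay apart on the first component by 61.4% of its range. Lower depth as the cause is argued against by a gap of 60.9% after thinning all libraries to 14549787 counts, and GC bias by a gap of 61.9% after the trend was removed. A share of fibroblasts, leukocytes or endothelial cells large enough to set the 4 apart is argued against by Col1a1, Col3a1, Ptprc and Pecam1, which reached at most 3.16 unscaled CPM in the 4 libraries. Other values go with such cells: the fibroblast list scored 0.24 to 0.53 in the 4 and −0.50 to 0.08 in the other 5, and Cd68 had 87.4 to 102 CPM against 8.50 to 45.1. Of the other leukocyte markers, however, Adgre1, C1qa and Tyrobp had 0 CPM in all 9 libraries, and Lyz2 had at most 0.282 CPM in the 4. Of the fibroblast list Dcn, at 733 to 3288 CPM, was abundant in all 9 libraries and did not divide this way. Its members Col1a1, Col3a1 and Mfap5 lay at 0.239 to 3.34 CPM, near the detection limit, and Col1a1 was highest in EpPT1 2, outside the 4. Other cell types were not tested. A culture state with more hypoxia genes, such as a difference in confluence or time at harvest, stays open as a hypothesis: the lowest glycolysis and hypoxia score of the 4 exceeded the highest of the other 5 by 0.39 (log2). Other lists divided alike, so this score does not single out hypoxia. Basal epithelium scored 0.39 to 0.60 against −0.61 to −0.20, and the unfolded protein response 0.26 to 0.66 against −0.37 to −0.26. Mitochondrial ribosomal RNA took 0.139% to 0.307% of counts against 0.0375% to 0.0657%, and RNA or library quality was not tested. No group of the design follows this split, so no effect of the light was tested for it. The 4 hold every library numbered 3 and also EpPT2 2, and the other 5 hold every library numbered 1. Whether libraries of one number were handled together was not tested.

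Other splits of the libraries into groups of 3 are too few, at 10 per comparison, for a share under 0.05. Genes called numbered 0 in the real split of EpPT1 and Ctrl and up to 1 in other splits (10 of 10 as large), 0 and 0 for EpPT2 and Ctrl (10 of 10), and 0 and 2506 for EpPT2 and EpPT1 (10 of 10). Lists numbered 0 and up to 16 (10 of 10), 4 and 16 (8 of 10), and 6 and 15 (10 of 10) in the same order. The 2506 genes came from setting EpPT1 3, EpPT2 2 and EpPT2 3 against EpPT1 1, EpPT1 2 and EpPT2 1. That division follows the mitochondrial share and points to a structure of the samples, but it was not refitted with the share as a covariate. In the real split of EpPT2 and EpPT1, edgeR called 0 genes with or without that covariate. Camera called 1 list with it and 6 without. For a difference in any group, 100 of 100 splits drawn from 280 gave at least the real 0 genes, and the highest gave 5981. Where the real count is 0 every split is as large by construction, so those counts say nothing about chance.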
